A study of Triticum aestivum with 6 samples.

How the data were processed

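The data are RNA-seq libraries from developing grain of bread wheat (Triticum aestivum), cultivar Banks. Aleurone, the outer cell layer or layers of the endosperm, and starchy endosperm, the inner storage tissue, were dissected by hand at 6, 9 and 14 days post anthesis (DPA). Per the series' design text, each preparation pooled at least 5 seeds from 3 spikes of 3 plants. There was 1 library per tissue and stage, 6 in all, and each library was treated as its own group. Per the labels' protocols, RNA was amplified linearly from an oligo-dT primer, the poly(A) tail was cut off with a restriction enzyme, the libraries were amplified by PCR for 15 cycles, and sequencing was on a Genome Analyzer IIx. The aligner, its settings and the version of the sequence set are not given in the sources used here.

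Each deposited file lists the same 221925 transcript sequences with their lengths (median 644 bases, range 100 to 7535). For each sequence the authors gave the count of total reads and the count of unique reads, and the unique count never exceeded the total. The authors also gave an RPKM value, the read count scaled by sequence length and library total. Recomputing RPKM from the total counts and lengths gave the deposited values to within 5e-04. The 2 files of the 6 DPA libraries also carried a transformed score per the file headers, within 0.002164 of the square root of RPKM, which was not used. Total read counts were analysed here because the authors' RPKM values rest on them, and unique read counts were an alternative. Reads that match several near-identical sequences are part of the total counts, how they were shared out is not given in the sources used here, and the values of homoeologues, paralogues and overlapping ESTs are uncertain for that reason. A sequence is not a gene: a gene can be represented by several sequences, so counts of sequences are not counts of genes.

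The identifiers are of 2 kinds. There were 93508 that begin with TC and 128417 others. None (0) matched any column of the reference gene table used here, and the files do not pair identifiers with gene names, functions or positions. The 35 gene and cell type marker lists fixed before the data were examined therefore matched 0 sequences, the planned set tests and marker checks were not run, and no chromosome position or annotation is given. The rule for named sequences had asked for a description of function. Without descriptions, the 2 sequences per direction with the largest fitted change are named for the tissue comparison and for 14 against 6 DPA, among those past the threshold with at least 50 reads in the highest library and the same direction at every stage or in both tissues.

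RPM below stands for reads of a sequence scaled to the library total, as in RPKM but without the length. Library totals ranged from 4104682 to 37911327 reads. A count of 3 reads, the limit that a count of 0 allows, corresponded to between 0.07913 and 0.7309 RPM. Intervals and floors cover counting error only, and PCR copies were not told apart. For tests, sequences with at least 10 reads in at least 3 libraries were kept (75040). Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) in a single model with tissue and stage as factors, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The model leaves 2 residual degrees of freedom. Its spread holds the difference between stages in the tissue effect as well as the difference between pools. The spread of each sequence was combined with one shared over sequences, which carried 6.683 prior degrees of freedom. A call means that the tissue difference was large against this combined spread, and not that it was repeated in separate plants. The common biological coefficient of variation was 0.5895. The samples pair by stage, as the labels give it, and stage was in the model from the start.

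Counts were simulated with the mean rate of each stage over both tissues and the fitted spread of each sequence. In these, 200 of the 75040 sequences were changed between tissues, drawn from those with a mean of at least 50 reads per library. The tissue test recovered 4% of 50 sequences changed 4-fold, 80% of 50 changed 16-fold and 100% of those changed 64-fold or 256-fold. There were 16 false calls among 74840 unchanged sequences. Recovery of changed sequences with fewer reads was not simulated. The test therefore had little power for changes of 4-fold. The recovered sequences numbered 2, 40, 50 and 50 at 4-fold, 16-fold, 64-fold and 256-fold. Set against these, the 16 false calls were a larger share of all calls in the simulation than the adjusted p threshold aims for.

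Comparisons of 2 libraries have no replicate check and carry no p-value. For these, sequences with at least 50 reads in the higher library were counted as changed when the scaled ratio was at least 4, with lower counts set at 3 reads. As depth differed between stages, the same counts were made after thinning all libraries at random to the smallest total of 4104682 reads, a step chosen after seeing the depths. Ratios of single sequences carry exact 95% intervals (Clopper-Pearson). Correlations were computed across sequences on log2 of scaled RPM plus 1, and sequences are not independent replicates.

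Alternatives were DESeq2 1.42.0 size factors in place of TMM, library totals, the DESeq2 Wald test, limma-voom (limma 3.58.1), no filter and a filter of 50 reads, leaving out the 100 most abundant sequences, each library or each stage, dropping stage or tissue from the model, other fold and read thresholds, unique reads and equal depth. The last 2 were added after the data were examined, as were 10 repeats of the thinning with other random draws. The planned pseudocount alternatives applied only to files without counts and were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.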

Results

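The transcripts of aleurone and starchy endosperm were compared at 6, 9 and 14 DPA. The 6 DPA libraries held 27150859 reads in aleurone and 30581013 in starchy endosperm. The 9 DPA libraries were shallower, at 4549034 and 4104682 reads. The 14 DPA libraries held 37911327 and 37502901 reads. The share of reads that the authors counted as unique was 52.2% and 52.9% at 6 DPA, 45.1% and 42.1% at 9 DPA and 50.1% and 42.8% at 14 DPA, in each case aleurone first. Comparisons with 9 DPA therefore set libraries of unlike depth against each other, while the 2 tissues of a stage had similar depths. With 1 pooled library per tissue and stage, values of single libraries have no replicate error.

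The starchy endosperm concentrated its transcripts in few sequences as the grain developed. In starchy endosperm the 100 most abundant sequences held 10.7% of reads at 6 DPA, 16.3% at 9 DPA and 32.3% at 14 DPA. In aleurone they held 8.76%, 11.1% and 15.2% at the same stages. At 14 DPA, 471 sequences sufficed for 50% of the starchy endosperm reads, against 3055 in aleurone, and at 6 DPA the numbers were 2943 and 4195. The most abundant single sequence took 1.82% of the 14 DPA starchy endosperm reads and 0.985% of the 14 DPA aleurone reads. On unique reads alone the top 100 held 25.03% in 14 DPA starchy endosperm and between 8.24% and 13.8% in the other 5 libraries. At an equal depth of 4104682 reads, 85737 sequences were detected by at least 1 read in 14 DPA starchy endosperm, the fewest, and 106330 in 9 DPA aleurone, the most.

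**Figure D1:**
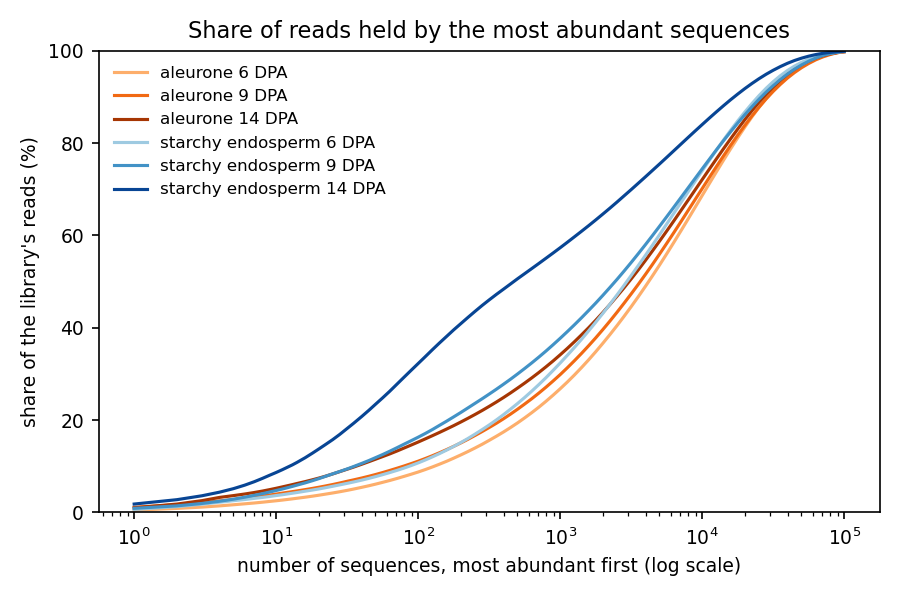
Cumulative share of each library's reads (%, vertical axis) held by its most abundant sequences (number of sequences, log scale, horizontal axis), 1 line per library. The 14 DPA starchy endosperm line reaches 32.3% at 100 sequences, and the other 5 lie between 8.76% and 16.3% there.

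The profiles grouped by tissue up to 9 DPA, and the 14 DPA aleurone stood between the tissues. The closest libraries were aleurone at 6 and 9 DPA, with a Pearson r across the 75040 tested sequences of 0.885 (Spearman rho 0.852). Starchy endosperm at 9 and 14 DPA followed, with r = 0.806 (rho 0.755). The 14 DPA aleurone correlated with 6 DPA aleurone at r = 0.702, with 6 DPA starchy endosperm at 0.711 and with 14 DPA starchy endosperm at 0.725. The younger aleurone libraries correlated with 14 DPA starchy endosperm at 0.510 and 0.480. At equal depth, and with it a different set of tested sequences, the 2 closest pairs gave 0.839 and 0.742, and 14 DPA aleurone correlated at 0.574 with 6 DPA aleurone, 0.544 with 6 DPA starchy endosperm and 0.585 with 14 DPA starchy endosperm. By Spearman's rho at equal depth the order turned, and 14 DPA aleurone was closer to 6 DPA aleurone than to 14 DPA starchy endosperm (rho 0.578) or 6 DPA starchy endosperm (rho 0.557). These are correlations across sequences of single libraries, and no test was made of their differences.

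**Figure D2:**
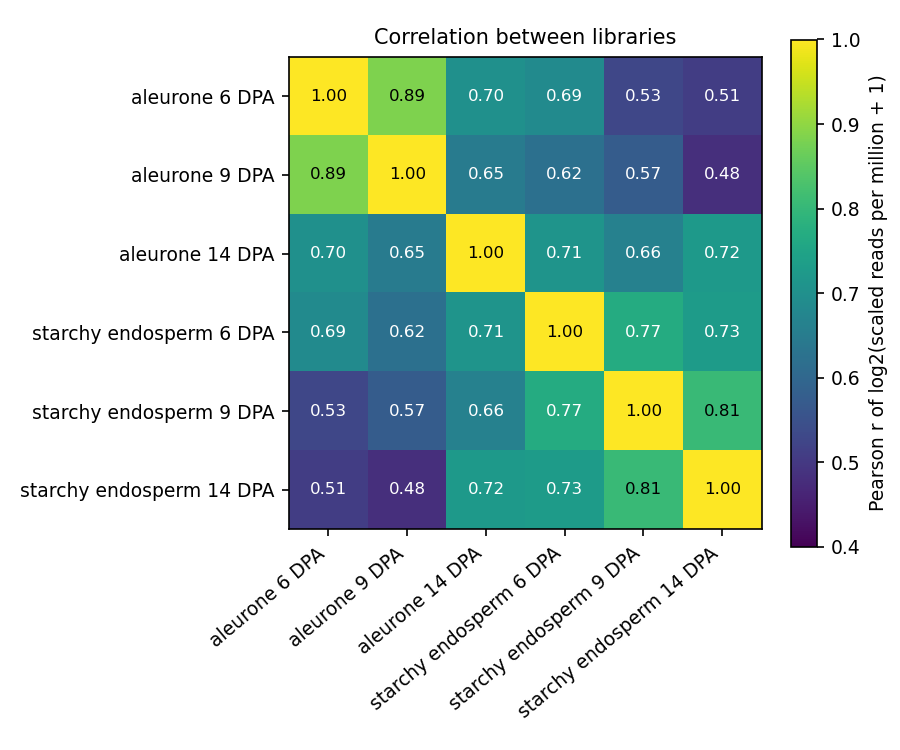
Pearson r between each pair of the 6 libraries, across 75040 sequences, on log2 of scaled RPM plus 1; the colour scale and the printed numbers give r. The highest value off the diagonal is 0.885, between aleurone at 6 and 9 DPA.

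The central comparison asked which transcripts distinguish aleurone from starchy endosperm through development. Over the 3 stages, 4574 of 75040 sequences differed between the tissues at an adjusted p under 0.05 in edgeR's quasi-likelihood test with stage in the model. Of these, 2543 were higher in aleurone and 2031 were higher in starchy endosperm. The direction was the same at all 3 stages for 2487 of the aleurone set and for 2031 of the starchy endosperm set, and 1908 and 1553 were at least 4-fold apart at every stage. A stage with 3 reads or fewer in both tissues took a negative log2 ratio from library size alone. Such a stage counted as higher in starchy endosperm, so the direction counts of the 2 sets are not alike. The spread of the test holds differences between stages, so the test itself favours sequences whose stages agree. The counts of direction and of 4-fold differences are therefore no independent evidence of agreement. The called differences were large, with a median absolute log2 fold change of 5.00 and a smallest one of 2.22. The aleurone set was a median 4.45 log2 units higher in aleurone at 6 DPA, 3.89 at 9 DPA and 3.32 at 14 DPA. For the starchy endosperm set the median log2 ratios of aleurone to starchy endosperm were -4.73, -4.06 and -4.48.

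The 2 sets held a larger share of their own tissue's transcripts at 9 than at 6 DPA, and at 14 DPA the aleurone set held less and the starchy endosperm set more than at 9 DPA. The 2543 sequences higher in aleurone held 16.5% of aleurone reads at 6 DPA and 19.5% at 9 DPA, but 3.84% at 14 DPA, and at most 0.493% of reads in any starchy endosperm library. The 2031 sequences higher in starchy endosperm held 13.3% of starchy endosperm reads at 6 DPA, 25.4% at 9 DPA and 48.4% at 14 DPA. In aleurone they held 0.358%, 0.535% and 2.80%. The sets were chosen on these same libraries, so the separation of the tissues in these shares is no independent evidence. The fall to 3.84% holds for the called set only, which was chosen on an effect over all 3 stages. At equal depth, 1105 sequences were at least 4-fold higher in 14 DPA aleurone than in each other library. These held 20.1% of that library's reads. Sequences with 10 reads in 14 DPA aleurone alone were not tested, as the filter asked for 3 libraries.

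Of the sequences higher in aleurone, TC372976 (1084 bases) had the largest fitted change. It had an RPKM of 115 at 6 DPA, 269 at 9 DPA and 0.316 at 14 DPA in aleurone and no reads in the 3 starchy endosperm libraries. The ratios of these sequences pool the reads of a tissue over the stages. With the 0 starchy endosperm reads of TC372976 set at 3, its ratio was 1229, with a lower exact 95% limit of 999.2. Its fitted log2 fold change was 13.66 (SE 1.40, adjusted p = 0.004706 in edgeR). The pooled ratio rests on 6 and 9 DPA, as TC372976 had 13 reads in 14 DPA aleurone. Of its aleurone reads, 562 of 3383 at 6 DPA and 168 of 1327 at 9 DPA were unique. On unique reads TC372976 had too few libraries to be tested. TC431027 (486 bases) ran the other way with stage, at 13.3, 20.8 and 134.7 RPKM in aleurone and no reads in starchy endosperm. With these set at 3 reads its ratio was 703, with a lower limit of 571.7 (edgeR adjusted p = 0.004604). Of the sequences higher in starchy endosperm, AL809947 (347 bases) had 34.0, 55.5 and 12.6 RPKM there and no reads in aleurone. With aleurone set at 3 reads its ratio was 258, with a lower limit of 209.1 (edgeR adjusted p = 0.005144). TC398156 (883 bases) had 43.6, 21.8 and 54.6 RPKM in starchy endosperm and 2 reads over the aleurone libraries, a ratio with an exact 95% interval of 542.9 to 16220 (edgeR adjusted p = 0.004369). With either 9 DPA library left out, none of these 4 sequences was called, as they either missed the threshold or had too few libraries to be tested.

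The number of tissue calls depended on single libraries. Without the 9 DPA aleurone library, without the 9 DPA starchy endosperm library or without both, edgeR called 0 sequences at the threshold, with 7820, 8113 and 7159 at an unadjusted p under 0.05. The count was 2278 without 6 DPA aleurone, where the balance turned to 1008 higher in aleurone and 1270 higher in starchy endosperm, 2404 without 6 DPA starchy endosperm, 0 without both (7222 unadjusted), 8622 without 14 DPA aleurone and 9611 without 14 DPA starchy endosperm. Scaled by library totals, the tissue test called 5584 sequences, of which 68.1% were higher in aleurone, against 55.6% with TMM.

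**Figure D3:**
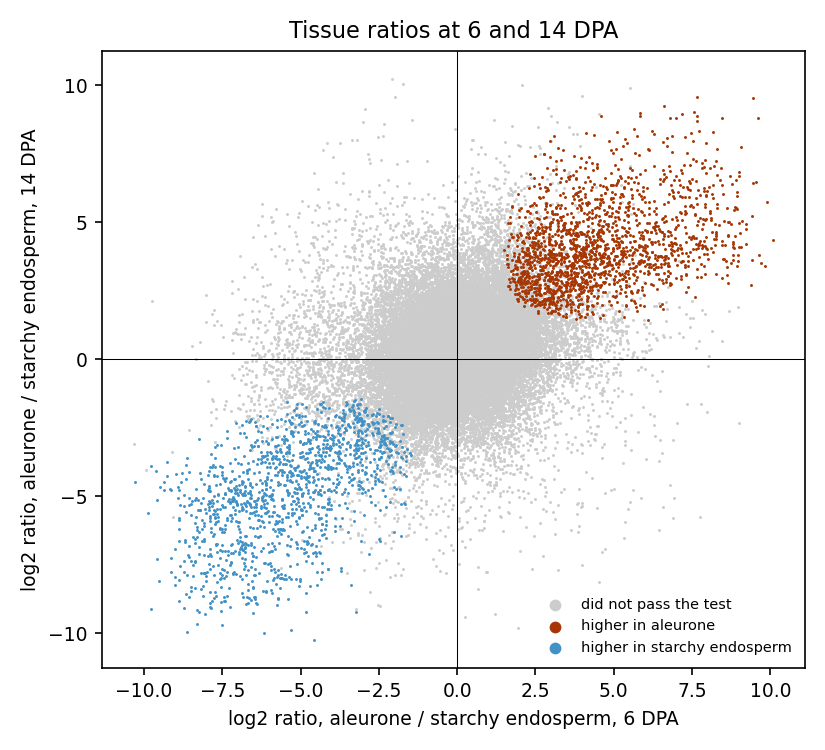
Log2 ratio of aleurone to starchy endosperm at 6 DPA (horizontal axis) and at 14 DPA (vertical axis) for 47346 sequences with at least 50 reads in a library of each stage; each point is a sequence, coloured by its call in the tissue test. The 1854 points higher in aleurone lie in the upper right and the 1407 points higher in starchy endosperm in the lower left. The calls were made on these same libraries, so this placement is no independent evidence.

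At each single stage the tissues differed for a large part of the sequences. At equal depth, 29.5% of the 21772 sequences considered were at least 4-fold apart at 6 DPA, 38.4% of 21384 at 9 DPA and 30.9% of 17910 at 14 DPA. At 6 DPA 3560 were higher in aleurone and 2866 in starchy endosperm, at 9 DPA 4764 and 3449, and at 14 DPA 3222 and 2305. At full depth the numbers 4-fold apart were 15314, 8553 and 15823. Scaling matters at 14 DPA: library totals moved all aleurone to starchy endosperm log2 ratios up by 0.69 relative to TMM, and the share of the 4-fold differences that were higher in aleurone went from 62.8% to 79.1%.

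The stage comparison asked how each tissue changed as the grain filled. Aleurone changed little from 6 to 9 DPA and much from 9 to 14 DPA, while starchy endosperm changed in both intervals. At equal depth, 8.94% of the sequences considered changed at least 4-fold between 6 and 9 DPA in aleurone and 32.9% between 9 and 14 DPA. In starchy endosperm the shares were 24.6% and 21.0%. Between 6 and 14 DPA they were 26.9% in aleurone and 30.03% in starchy endosperm. In starchy endosperm, 2019 sequences rose and 3251 fell at least 4-fold from 6 to 14 DPA, and in aleurone 2900 rose and 2948 fell. With 1 library per group these are differences between libraries, and counts at full depth were one-sided for every comparison with 9 DPA because the read minimum favours the deeper library. With library totals, all log2 ratios of 14 to 9 DPA in starchy endosperm moved by -0.75, and those of 14 to 6 DPA by -0.62. At full depth the share of 4-fold changes that were rises then went from 82.4% to 48.4% for 14 against 9 DPA and from 40.2% to 21.8% for 14 against 6 DPA in starchy endosperm.

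**Figure D4:**
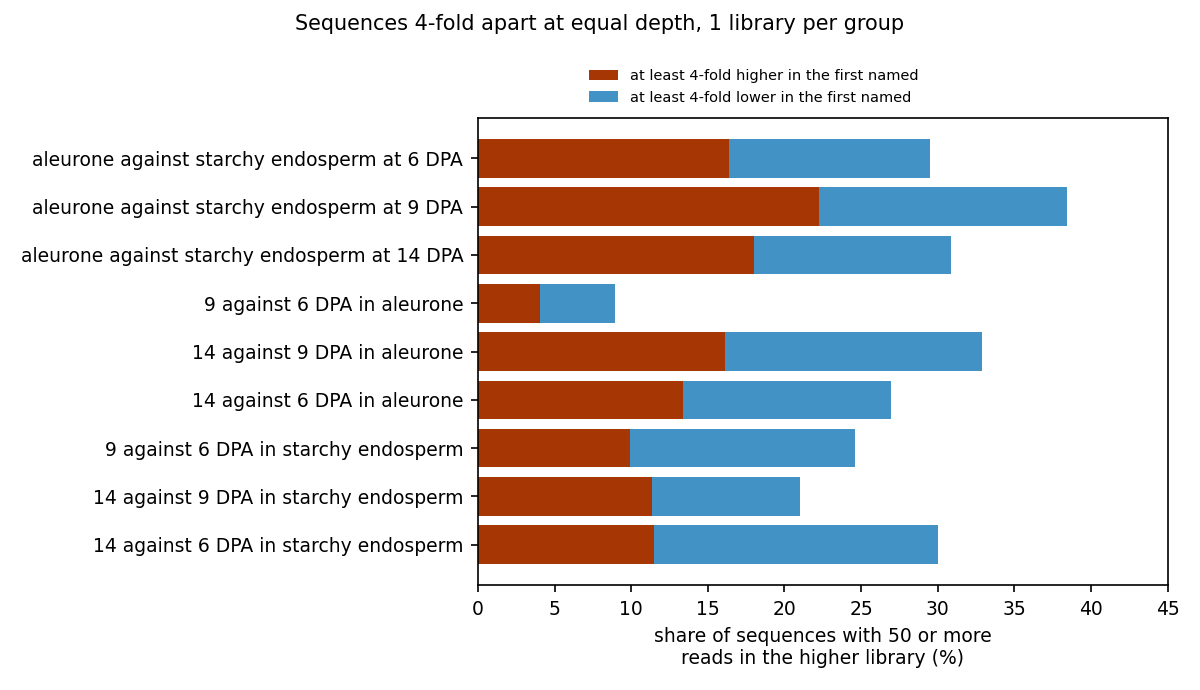
Share of sequences at least 4-fold apart (%, horizontal axis) in each pair of libraries at an equal depth of 4104682 reads, among sequences with at least 50 reads in the higher library; red is higher and blue lower in the library named first. Aleurone at 9 against 6 DPA has the smallest total, 8.94%.

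Averaged over both tissues, 818 sequences changed from 6 to 14 DPA in edgeR's quasi-likelihood test with tissue in the model, at an adjusted p under 0.05. Of these 438 rose and 380 fell, with a median absolute log2 fold change of 7.84. Sequences with at least 10 reads at a single stage only could not be tested in any stage comparison. The filter asked for 3 libraries, and each stage had 2. The direction was the same in both tissues for 438 of those that rose and 370 of those that fell, and 422 and 303 changed at least 4-fold in both. A tissue with 3 reads or fewer at both stages took its direction from library size alone. The test also favours sequences whose tissues agree, as its spread holds differences between tissues in the stage change. The 438 that rose went from 0.122% to 16.9% of the reads in starchy endosperm and from 0.00464% to 0.993% in aleurone. The 380 that fell went from 3.35% to 0.0193% in starchy endosperm and from 3.74% to 0.0136% in aleurone. Of the 438 that rose, 388 were also called higher in starchy endosperm, where independent lists would share 11.8, and 2 were called higher in aleurone, where independent lists would share 14.8. Of the 380 that fell, 147 were also called higher in aleurone and 156 higher in starchy endosperm, with 12.9 and 10.3 for independent lists. Both tests use the same libraries and the same spread per sequence, and no test was made of these overlaps.

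TC390892 (657 bases) had the largest fitted rise, from no reads at 6 DPA to 649 RPKM in starchy endosperm and 11.2 RPKM in aleurone at 14 DPA (log2 fold change 15.71, SE 1.67, adjusted p = 0.02389 in edgeR). With 6 DPA set at 3 reads the ratio was 5209, with a lower exact 95% limit of 4236. This and the ratios below pool the reads of both tissues at a stage. At 14 DPA only 973 of its 15990 starchy endosperm reads and 36 of its 278 aleurone reads were unique. On unique reads TC390892 had too few libraries to be tested. TC409899 (929 bases) went from no reads to 212.9 and 17.4 RPKM. With 6 DPA set at 3 reads its ratio was 2572, with a lower limit of 2091 (edgeR adjusted p = 0.02446). TC395064 (857 bases) went from 669 RPKM in aleurone and 1.76 in starchy endosperm at 6 DPA to no reads in either at 14 DPA. With 14 DPA set at 3 reads its ratio of 6 to 14 DPA was 5415, with a lower limit of 4404 (edgeR adjusted p = 0.02446). TC407261 (886 bases) fell from 3160 RPKM in aleurone and 4.17 in starchy endosperm to 0.149 RPKM and no reads, a ratio with an exact 95% interval of 6792 to 48820 (edgeR adjusted p = 0.04069). Of its 76023 reads in 6 DPA aleurone, 5058 were unique. At 6 DPA TC395064 and TC407261 had 46 and 113 reads in starchy endosperm, against 15561 and 76023 in aleurone. Carry-over of aleurone RNA was not tested for these 2 sequences, so a fall in starchy endosperm itself is not established.

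The 14 against 6 DPA calls were fragile. The count went to 0 without the 9 DPA aleurone, the 9 DPA starchy endosperm or the 6 DPA starchy endosperm library, to 238 without 6 DPA aleurone, to 2473 without 14 DPA aleurone and to 5047 without 14 DPA starchy endosperm. With library totals 1045 sequences were called, of which 42.4% rose, against 53.6% with TMM. Which direction held more calls was not stable: among the alternatives that gave calls, the share that rose ran from 39.0% without 14 DPA aleurone to 76.4% at equal depth. No sequence (0) passed for 9 against 6 DPA or for 14 against 9 DPA in edgeR, with 6776 and 10614 at an unadjusted p under 0.05. The DESeq2 Wald test called 1583 and 4481 in those 2 comparisons and limma-voom called 0 in each.

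The change from 6 to 14 DPA differed between the tissues for many sequences, although with 1 library per tissue and stage a full interaction leaves no residual, and no interaction was tested. Among 46171 sequences with at least 50 reads in a library of each tissue, 4624 rose and 3587 fell at least 4-fold in aleurone, and 3789 rose and 6485 fell in starchy endosperm. There were 1457 that rose in both and 1492 that fell in both. Another 351 rose in aleurone and fell in starchy endosperm, and 217 did the reverse. The log2 changes of the tissues correlated at r = 0.43 across these sequences. In terms of tissue preference, 507 of 47346 sequences were at least 4-fold higher in starchy endosperm at 6 DPA and at least 4-fold higher in aleurone at 14 DPA, and 201 switched the other way. By comparison, 2341 were 4-fold higher in aleurone at both stages and 1761 were 4-fold higher in starchy endosperm at both.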

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

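Between 6 and 14 DPA, 568 of the 46171 sequences considered changed at least 4-fold in opposite directions in the tissues, 351 up in aleurone and down in starchy endosperm and 217 the reverse. They were picked out because the libraries of one tissue moved one way and those of the other moved the opposite way. The difference was not tested, since there was 1 library per tissue and stage. More sequences changed at least 4-fold in the same direction in both tissues, 1457 up and 1492 down. The log2 changes of the tissues correlated at r = 0.43. The 568 were not set against the number that unrelated changes would give, so they are not shown to be an excess.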

How the results depend on the processing

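The unique-read and equal-depth alternatives, the repeated thinnings included, were chosen after seeing the data. The tissue count (4574) stayed within 1.5 times under DESeq2 size factors (4378), library totals (5584), limma-voom (5660), removal of the 100 most abundant sequences (4419), unique reads (3706), equal depth (3561) and without both 14 DPA libraries (6469), and 4306 to 4545 of the 4574 were called again under size factors, totals, limma-voom and the removal. The DESeq2 Wald test called 10502 and no filter 12014, a filter of 50 reads in 3 libraries 2594, and the fit without both 6 DPA or without both 9 DPA libraries 0. Samples were paired by stage in the reported fit; with no replicate block, that is without stage in the model, 450 were called, all among the 4574. Leaving out 1 library gave 0 to 9611, with 1 residual degree of freedom, and the lone library of a stage then carried no information on tissue. For 14 against 6 DPA (818), the Wald test called 5071, limma-voom 1582, no filter 7214, the 50-read filter 105, equal depth 267, and the fit without tissue in the model 0; leaving out 1 library gave 0 to 5047. For 9 against 6 DPA (0), the Wald test called 1583, no filter 2068, and leaving out 1 library gave 0 to 1849. For 14 against 9 DPA (0), these were 4481, 6408 and 0 to 5914. Over 10 random thinnings to equal depth the tissue count was 3050 to 3561 and that of 14 against 6 DPA 0 to 270. The cause of these moves was not tested. No alternative in which they could be tested reversed the direction of the 8 named sequences, and 21 of their 95 alternative values missed the threshold. The 8 sequences were picked for the same direction throughout, so a reversal was unlikely. Alternatives in which a sequence was left out or fell short of the filter gave no value. Among these were unique reads for TC372976, TC390892 and TC407261.

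Counts of sequences 4-fold apart in 2 libraries follow the thresholds by construction. At 2-fold, the tissues differed for 30250, 14238 and 30553 sequences at 6, 9 and 14 DPA. In aleurone 13890, 26312 and 30334 changed for 9 against 6, 14 against 9 and 14 against 6 DPA, and in starchy endosperm 20999, 17571 and 28963. With a minimum of 10 reads the tissue numbers were 24625, 18351 and 23876, those of 9 against 6 and 14 against 6 DPA in aleurone 6827 and 25089, and those of 14 against 9 and 14 against 6 DPA in starchy endosperm 11267 and 23174. With 200 reads they were 8342, 3044 and 8589 between tissues, 1809, 7239 and 8200 in aleurone and 5199, 3712 and 7599 in starchy endosperm. At equal depth they were 6426 and 5527 between tissues at 6 and 14 DPA, 1789, 7118 and 5848 in aleurone and 4754, 3444 and 5270 in starchy endosperm. On unique reads they were 5088 between tissues at 9 DPA, 2274 and 8218 for 9 against 6 and 14 against 9 DPA in aleurone, and 5763 and 4747 for the same steps in starchy endosperm. Under library totals these totals stayed within 1.5 times, while the balance of rises and falls moved as given in the report, and the 568 opposite changes became 675. The depth of the 9 DPA libraries limits every comparison with them: 3 reads there stand for 0.6595 and 0.7309 RPM, against 0.07913 to 0.1105 in the others. Pseudocount alternatives and gene list tests were not run, as counts were at hand and no list member could be matched.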

Other observations

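The 14 DPA aleurone library had the largest number of sequences of its own, and 14 DPA starchy endosperm the largest share of reads in such sequences. At equal depth, 1105 sequences were at least 4-fold higher there than in each of the other 5 libraries, and they held 20.1% of its reads. Starchy endosperm at 14 DPA followed with 629 such sequences and 28.1% of its reads. At 6 DPA there were 120 in aleurone (0.907% of reads) and 527 in starchy endosperm (6.49%), and at 9 DPA 347 in aleurone (4.98%) and 228 in starchy endosperm (1.26%). Of the 1105 sequences raised in 14 DPA aleurone, 387 were outside the tests because too few libraries had 10 reads. Untested sequences took 8.38% of the 14 DPA aleurone reads, of which the 10 most abundant took 3.26% of the library, and between 1.23% and 3.59% of reads in the other libraries.

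A minority of the transcripts abundant in one tissue were nearly missing from the other. Of 1434 sequences at 100 or more RPM in 6 DPA aleurone, 248 were under 1% of that level in 6 DPA starchy endosperm. At 9 DPA it was 344 of 1413 and at 14 DPA 119 of 1277. In the other direction, 163 of 1604, 163 of 1329 and 53 of 1016 sequences abundant in starchy endosperm were under 1% of that level in aleurone. The median ratio was 43.5%, 17.3% and 29.1% at 6, 9 and 14 DPA for aleurone sequences measured in starchy endosperm, and 40.8%, 25.3% and 17.03% for starchy endosperm sequences measured in aleurone. The 5th percentile of these ratios was 0.230%, 0% and 0.377% at 6, 9 and 14 DPA for aleurone sequences measured in starchy endosperm, and 0.550%, 0.316% and 0.969% at 6, 9 and 14 DPA for starchy endosperm sequences measured in aleurone. RNA of the average profile of one tissue that was carried into the other preparation would set a lower limit to these ratios.

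Of the tests below, the one on the sequences that rose in both tissues and the repeated thinnings were chosen after the result was seen. The 14 DPA aleurone library correlated with 14 DPA starchy endosperm more than the younger aleurone libraries did, by 0.215 in r over the closer of these. Carry-over of RNA with the profile of the starchy endosperm library was tested by removing it at 0.969%, the 5th percentile ratio, after which r was 0.711 against 0.725 before. Removal at the 25th percentile, 4.42%, left r at 0.662. On unique reads the excess was 0.243, which argues against reads shared between near-identical sequences. The 14 DPA aleurone was also closer than the younger aleurone libraries to starchy endosperm of other stages, at 0.664 against 0.528 and 0.574 with that of 9 DPA and 0.711 against 0.687 and 0.621 with that of 6 DPA. Adjoining endosperm cells with another profile and a change of the aleurone with age stay open and untested. Other tissue that hand dissection could bring along, such as pericarp or other maternal tissue, could not be checked in any library. The marker lists planned for that check matched no sequence.

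The 438 sequences that rose from 6 to 14 DPA in both tissues were mostly higher in starchy endosperm, at a median aleurone to starchy endosperm ratio of 5.14% at 14 DPA. Carry-over of the starchy endosperm profile is a candidate explanation for their rise in aleurone. After removal of carry-over at 0.969%, 385 of them, 87.9%, were still at least 4-fold higher at 14 than at 6 DPA in aleurone. After removal at 4.42%, the 25th percentile, 214 of them, 48.9%, were, so the outcome depends on the ratio removed. Carry-over of the library's own profile at 4.42% would leave no abundant sequence far below that ratio. Of 1016 such sequences 53 were under 1%, which argues against carry-over of this profile at 4.42%. This count cannot judge removal at 0.969%, which is itself the 5th percentile of the same 1016 ratios. Their 1st percentile was 0.384%. On unique reads the 5th percentile ratio was 0.728% over 1167 sequences. Carried-over cells with a profile other than the average of the starchy endosperm remain open, as does a rise in the aleurone itself, which was not tested, and the marker lists that might separate them from aleurone could not be matched.

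No sequence (0 in edgeR) passed between 9 DPA and either other stage, while 14 against 6 DPA gave 818, and the low depth of the 9 DPA libraries is a possible explanation. With all libraries thinned to 4104682 reads, 14 against 6 DPA gave 267 calls among 41995 sequences tested, of which 246 were among the 818, and the comparisons with 9 DPA gave 0 each (3555 and 5638 unadjusted). Over 10 random thinnings 14 against 6 DPA gave 0 to 270 calls, and the comparisons with 9 DPA gave 0 in each. The test for low depth as the whole cause asked whether 14 against 6 DPA lost its excess in at least 1 thinning, and it did in 2, where the lowest count was 0. That bound is lenient, as each of the others gave 207 or more calls, so low depth as the whole cause is not excluded and not established, and a difference of development between the stages stays open and untested. The unadjusted count for 14 against 9 DPA, 10614, was above that for 14 against 6 DPA, 9303.

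The tissue test was repeated for each of the 10 splits of the 6 libraries into 3 and 3, with stage in the model. The real split gave 4574 calls, 1 of the 10 splits reached that number, and the highest of the others gave 0. There are too few splits for a share under 0.05. Among the 4 splits that part all 3 stage pairs, the other splits also gave 0 at most. Tissue was not in the models of the other splits, so the tissue difference entered their spread. Few or no calls were therefore likely in them, and no conclusion is drawn from the 0. The splits that part only 1 stage pair also repeat each other, as with stage in the model they compare the same 2 libraries.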
